A study of Mus musculus with 34 samples.

How the data were processed

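RNA sequencing of total RNA was carried out on mouse mammary adenocarcinoma cells of the 3617 line, in which the endogenous glucocorticoid receptor (GR, gene Nr3c1) had been knocked out and GFP-tagged mouse GR stably expressed instead. The labels name 5 receptor forms: wild type (WT), Y551A, Y551A-Dim, D647V and D647V-Tetra. They do not say what Dim and Tetra stand for, so the names are used as given. The labels give 10% serum and 5 ug/ml tetracycline for every library. Cells received 100 nM dexamethasone (Dex), a synthetic glucocorticoid, or its ethanol vehicle (EtOH) for 2 h. The 34 libraries form 12 groups in 2 library sets. Set 1 holds WT, Y551A and Y551A-Dim with 3 libraries per line and treatment. Set 2 holds a separate WT with 2 libraries per treatment, and D647V and D647V-Tetra with 3 each. The labels describe 2 batches made with different stranded total RNA kits but do not assign the libraries to them. All 16 column headers of set 2, and none of set 1, carry the word "resent". Lines of different sets were therefore compared only through the WT of their own set. The labels give a single line per receptor form. Effects of a substitution therefore cannot be told apart from other differences between lines, such as baseline expression or the level of the receptor transcript. The labels do not say whether replicates came from separate cultures, and if they did not, the p-values measure only the spread between preparations of the same culture.

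Per the labels, the authors trimmed 100 bp paired reads with cutadapt, aligned them to mm10 with STAR and counted exonic reads per gene name with featureCounts 2.0.3 on the GENCODE vM21 annotation, with reverse-stranded counting (option 2). The deposited values are raw counts of reads per gene name, per the file headers, with both mates of a pair counted, and no normalization. The table lists 55341 gene names, of which 55233 match a single gene and 108 are shared by several gene identifiers. Library totals ran from 44998213 to 70124595 counted reads in set 1 and from 60277930 to 79776573 in set 2. A spike-in of 5% Drosophila S2 cells is described in the labels. The counted table holds mouse genes, so scaling by spike-in reads was not used here.

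Counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with edgeR's filterByExpr, libraries were scaled by the trimmed mean of M-values (TMM), and edgeR's quasi-likelihood test was run on a model with a mean per group. Set 1 (18 libraries, 16140 genes, 12 residual degrees of freedom) and set 2 (16 libraries, 17535 genes, 10 residual degrees of freedom) were fitted separately. The 10 WT libraries of both sets were fitted together with 16540 genes and 6 residual degrees of freedom. The biological coefficient of variation was 5.13% in set 1, 8.62% in set 2 and 5.54% in the WT model. The 18 planned contrasts were the Dex response of each line, that of WT over both sets, the differences between Dex responses, and the EtOH baselines of each mutant against the WT of its set. P-values were two-sided and Benjamini-Hochberg adjusted over all genes of a contrast. A gene was called at an adjusted p below 0.05, with no fold minimum unless a 1.5-fold minimum is stated. Changes are log2 fold changes from edgeR's quasi-likelihood fit at its default prior count. A prior count of 2 was used only for log2 CPM values. The SE given with a change is its absolute value divided by the square root of the quasi-likelihood F statistic. Levels are CPM, counts scaled to the normalized library size, with SD.

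The lines, groups, contrasts, gene lists, named-gene rule and a list of other settings were fixed before the data were examined. For Dex contrasts, the rule names the 8 called genes with the highest and the 8 with the lowest change among those with an average log2 CPM of at least 1 and no overlap between the groups. For baselines it names 6 and 6 by the same criteria, and for differences of response 6 and 6 without the overlap criterion. Predicted and clone-named genes are passed over. Nr3c1, Hras (the parental cells carry a Dex-responsive MMTV promoter array driving a ras gene), Per1, Tsc22d3, Fkbp5, Sgk1, Dusp1, Lcn2, Mt1, Tgm2, Glul, Cdkn1a, Ccl2, Cxcl1, Ptgs2, Fos and Myc are named besides, as are list members with the lowest adjusted p. Zbtb16, Mt2 and Il6 were on that list too and did not pass the low-count filter. Genes named outside the rule are said to be so.

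The 23 gene lists cover classic GR-induced genes, inflammatory and NF-kB targets, immediate early and AP-1 genes, growth factor feedback, circadian clock, GR chaperones and cofactors, glucose and glutamine metabolism, cholesterol synthesis, cell cycle, p53 targets, integrated stress response, unfolded protein response, interferon response, YAP and TGF-beta targets, extracellular matrix, luminal and basal mammary epithelium, fibroblasts, immune cells, mitochondrially encoded genes, ribosomal proteins, structural non-coding RNA and replication-dependent histones. Each was tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the 23 lists. List p-values in the text are camera adjusted p-values unless stated otherwise. For transfer lists, the WT libraries of each set were fitted alone. Genes called there with a change of at least 1.5-fold were tested in the other set, where measured, with limma's fry. It asks whether a list moves on balance in a single direction, with Benjamini-Hochberg adjustment over the 12 tests of differences between lines.

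The other settings fixed at the start were DESeq2 size factors in edgeR, DESeq2 as the tool, no low-count filter, the replicate number as a block, only the groups compared, all 34 libraries in 1 fit, other fold minimums for the transfer lists, an estimated correlation for the list tests, and each library left out in turn. Where that left a group with 1 library, its spread was taken from the other groups. No pairing of the libraries by replicate number was seen. The median correlation of deviations between libraries of the same number was -0.011 in set 1 and -0.127 in set 2. Between libraries of different numbers it was 0.014 and 0.047. In simulated paired data it was 0.817. The simulated shared deviations were larger than the biological coefficient of variation of set 1, so weaker pairing cannot be excluded. Settings added after the data had been examined were per-library offsets over transcript length and GC content (splines with 4 degrees of freedom), the same with the replicate block, a covariate for the leading axis of within-group variation in set 2, and leaving out D647V-Tetra EtOH replicates 1 and 3. The model was tested on simulated counts with 200 changed genes per contrast. These were drawn from genes with an average log2 CPM of at least 1, so the shares called do not cover genes below that level. At a true change of 1.5-fold, 92% of changed genes were called in the WT design of set 1, 84% in that of set 2 and 66% for the difference between D647V-Tetra and WT. At 1.3-fold these shares were 82%, 52% and 20%. Unchanged genes made up 1.44% to 7.11% of calls. The simulated counts held no variation shared between genes of a library. In the data a leading axis held 16.9% of the within-group variance in set 1 and 42.3% in set 2. The simulated shares therefore need not hold for the data, least of all for set 2.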

Results

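Gene expression was measured in 34 total RNA libraries from GR-knockout mouse mammary adenocarcinoma cells that express GFP-tagged GR as WT, Y551A, Y551A-Dim, D647V or D647V-Tetra, after 2 h of 100 nM Dex or EtOH. Set 1 had 18 libraries with 44998213 to 70124595 counted reads each, and set 2 had 16 with 60277930 to 79776573. Each group had 3 libraries except the WT groups of set 2, which had 2. Between 20146 and 21674 genes had a count in the libraries of set 1, and between 21231 and 23005 in set 2. The series concerns multivalency of the GR ligand-binding domain, and the comparisons ask how far each receptor form transmits the early Dex response of WT.

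The receptor transcript itself, Nr3c1 (mm10 chromosome 18, 39410545 to 39519421), was detected in every library, at 234.4 to 380 CPM. In EtOH it stood at 280 ± 5.81 CPM in WT (SD, n = 3), 0.30 ± 0.031 log2 higher in Y551A (SE, n = 3 per group) and 0.15 ± 0.031 higher in Y551A-Dim. In set 2 it was lower than in WT by -0.24 ± 0.045 in D647V and -0.37 ± 0.045 in D647V-Tetra (SE, n = 3 against 2). All 4 baseline differences were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counts per gene name do not separate endogenous from introduced receptor transcripts.

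The first question was what Dex does within 2 h through the WT receptor. In set 1 (n = 3 per group), Dex raised Lcn2, an iron-siderophore-binding acute-phase protein, by 5.36 ± 0.322 log2 (SE) and Ccn2, the matrix-associated connective tissue growth factor, by 4.59 ± 0.057. Ccn2 lies on mm10 chromosome 10 (24595442 to 24598683), Sgk1 on the same chromosome (21882184 to 21999903), Lcn2 on chromosome 2 (32384633 to 32388252), Orm3 on chromosome 4 (63356162 to 63359511), Tsc22d3 on chromosome X (140539528 to 140600659), Hras on chromosome 7 (141189105 to 141194005) and Ccl2 on chromosome 11 (82035571 to 82037453). Lcn2 was near 0 in EtOH, at 0.2059 ± 0.0725 CPM against 8.421 ± 1.28 CPM with Dex (SD), so its changes rest on few EtOH reads here and in the other lines. Mean Ccn2 went from 11.99 ± 0.83 to 288.8 ± 5.48 CPM (SD). The clock repressor Per1 rose by 3.06 ± 0.129, the fatty acid carrier Fabp4 by 3.04 ± 0.153. The SOCS-box protein Spsb1 rose by 2.55 ± 0.078, the acute-phase protein Orm3 by 2.55 ± 0.114 and the calcium-binding S100a7a by 2.49 ± 0.171. The kinase Sgk1 rose by 2.42 ± 0.038 (from 148.1 ± 1.91 to 790.4 ± 2.52 CPM), and Tsc22d3 (GILZ) by 2.404 ± 0.051. The metal-binding Mt1 (1.27 ± 0.125), the Hsp90 co-chaperone Fkbp5 (1.02 ± 0.046), the MAP kinase phosphatase Dusp1 (0.97 ± 0.070) and glutamine synthetase Glul (0.85 ± 0.050) rose less, as did the cell cycle inhibitor Cdkn1a (0.59 ± 0.060) and transglutaminase Tgm2 (0.53 ± 0.038). The largest decreases were in the urokinase gene Plau (-0.91 ± 0.073), the kinase Plk2 (-0.86 ± 0.042), the transcription factor Snai2 (-0.79 ± 0.096) and Phlda1 (-0.77 ± 0.074). The stress gene Gadd45a (-0.73 ± 0.065), Ankrd1 (-0.71 ± 0.037), the lectin Clec2d (-0.65 ± 0.141) and the EGF-family ligand Hbegf (-0.64 ± 0.071) followed. The cyclooxygenase Ptgs2 fell by 0.49 ± 0.051, the chemokine Ccl2 by 0.37 ± 0.077 and Myc by 0.31 ± 0.055. Hras rose by 0.21 ± 0.040 (adjusted p = 0.00142 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Fos, at -0.34 ± 0.277, was not called (adjusted p = 0.768 by the same edgeR test). In total 549 genes were called, 323 up and 226 down, of which 153 changed at least 1.5-fold (136 up and 17 down). The count was 848 when only the WT libraries were fitted, and Clec2d was not called without WT Dex replicate 1 (-0.54).

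Of the 32 measured classic GR-induced genes, 23 rose and 1 fell in WT of set 1 (26 and 2 adjusted over the list alone), with a median of 0.82 and camera adjusted p = 5.98e-237 (limma). Errfi1, a feedback inhibitor of the EGF receptor (1.49 ± 0.044), and Ampd3 (1.65 ± 0.057) were among them. The growth factor feedback list fell, 10 of 21 with none rising (13 adjusted over the list alone, adjusted p = 4.37e-15 by limma's camera), including the phosphatases Dusp4 (-0.62 ± 0.060) and Dusp10 (-0.49 ± 0.052). Errfi1 and Dusp1, which rose, were not on that list, so not every feedback gene fell. Immediate early and AP-1 genes fell as a list, 11 of 24 down and 1 up (15 and 3 adjusted over the list alone), with Ier3 at -0.55 ± 0.063 and Klf10 at -0.48 ± 0.059. Inflammatory and NF-kB targets were called down, 5 of 22 falling and 1 rising (8 and 2 adjusted over the list alone), with Irf1 at -0.52 ± 0.050 and Csf1 at -0.38 ± 0.036. The member that rose was the chemokine Cxcl1 (0.56 ± 0.117), whose call was lost without WT Dex replicate 1 (0.45). In the circadian clock list 4 of 18 rose and none fell (4 and 0 adjusted over the list alone), with Per2 at 0.73 ± 0.064 and Nfil3 at 0.57 ± 0.057. These 5 lists and the luminal mammary epithelium list, where 1 of 6 rose (1 adjusted over the list alone), kept their calls with an estimated correlation, at limma's adjusted p between 3.63e-08 and 0.0419. YAP and TGF-beta targets split, with 4 of 23 up and 9 down (5 and 10 adjusted over the list alone), so that the median was -0.15 while the mean was 0.154 and camera called the list up (adjusted p = 0.106 with an estimated correlation, limma).

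Other lists were called down in WT of set 1 only with the preset correlation. They were the integrated stress response (3 of 18 down, 8 adjusted over the list alone, adjusted p = 0.0583 with an estimated correlation, limma), cholesterol synthesis (2 of 25 down, 2 adjusted over the list alone, adjusted p = 0.76 with an estimated correlation, limma), fibroblast markers (2 of 13 down, 5 adjusted over the list alone, adjusted p = 0.0566 with an estimated correlation, limma) and replication-dependent histones (3 of 66 down, 7 adjusted over the list alone, adjusted p = 0.516 with an estimated correlation, limma). No call was made for p53 targets (3 of 19 up and 2 down, 4 and 2 adjusted over the list alone), glucose and glutamine metabolism (2 of 24 up and 2 down, 2 and 2 adjusted over the list alone), GR chaperones and cofactors (1 of 26 up, 2 adjusted over the list alone), the unfolded protein response (1 of 18 up, 1 adjusted over the list alone) or extracellular matrix (1 of 24 up, 1 up and 1 down adjusted over the list alone). None of the 30 cell cycle genes, 16 interferon genes, 5 basal epithelial markers, 6 immune cell markers, 14 mitochondrially encoded genes, 33 ribosomal protein genes or 18 structural non-coding RNAs passed edgeR's test over all genes. Adjusted over the list alone, 1 basal marker fell, and 1 structural RNA rose and 2 fell.

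The WT response was measured again in set 2 (n = 2 per group). Lcn2 rose by 5.88 ± 0.363 (SE), Ccn2 by 4.98 ± 0.080, Orm3 by 3.90 ± 0.138, S100a7a by 3.16 ± 0.256, Per1 by 3.09 ± 0.170, Fabp4 by 2.80 ± 0.230, Spsb1 by 2.65 ± 0.104, Sgk1 by 2.65 ± 0.055 and Tsc22d3 by 2.55 ± 0.068. Smaller increases were in Mt1 (1.58 ± 0.076), Fkbp5 (1.21 ± 0.064), Dusp1 (1.11 ± 0.111), Glul (0.98 ± 0.050), Tgm2 (0.80 ± 0.074), Cdkn1a (0.76 ± 0.105) and Hras (0.48 ± 0.072). Dusp4 (-0.89 ± 0.068), Plk2 (-0.84 ± 0.061), Phlda1 (-0.79 ± 0.097), Plau (-0.71 ± 0.103) and the growth arrest gene Gas1 (-0.69 ± 0.085) fell. Ptgs2 (-0.10 ± 0.063, adjusted p = 0.68) and Myc (-0.11 ± 0.087, adjusted p = 0.757), which fell in set 1, did not pass edgeR's test here. Ccl2 fell (-0.40 ± 0.093), a call lost without WT EtOH replicate 1 (-0.24), Dex replicate 1 (-0.40) or Dex replicate 2 (-0.40). edgeR called 302 genes, 236 up and 66 down, or 200 without WT Dex replicate 1 of set 2. Of 583 genes called in either set and tested in both, 567 had the same sign, with r = 0.787 and rho = 0.905 across genes, which are not independent replicates. Up lists shared 205 genes and down lists 59, against 4.7 and 0.9 for independent lists. Among lists in WT of set 2, classic GR-induced genes rose (23 of 32 up and 1 down, 26 and 1 adjusted over the list alone, median 0.95), 7 of 22 growth factor feedback genes fell (10 adjusted over the list alone) and 4 of 18 clock genes rose (4 adjusted over the list alone), at adjusted p = 2.38e-07, 0.00601 and 0.045 with an estimated correlation (limma). YAP and TGF-beta targets split again (4 of 23 up and 3 down, 4 and 5 adjusted over the list alone, median -0.11, mean 0.266) and were called up (adjusted p = 0.00502 with an estimated correlation, limma). Immediate early genes were called down (6 of 24, 7 down and 1 up adjusted over the list alone) at adjusted p = 0.0565 with an estimated correlation (limma). Inflammatory and NF-kB targets, called down in set 1, went both ways and were not called (2 of 22 up and 2 down, 3 and 4 adjusted over the list alone, adjusted p = 0.891 with an estimated correlation, limma). As a difference between sets this list was called higher in set 2 without a member passing over all genes (2 of 22 adjusted over the list alone, adjusted p = 0.219 with an estimated correlation, limma), and it was not called without WT Dex replicate 1 of set 2 (limma adjusted p = 0.127). Irf1 (-0.51) and Ccl2 fell, while Tnfaip3 (0.475 ± 0.084, adjusted p = 0.00333 by edgeR) and Cxcl1 (0.57) rose, and Cxcl1 lost its call without WT EtOH replicate 2 (0.35), Dex replicate 1 (0.448) or Dex replicate 2 (0.68). Cell cycle, integrated stress response and luminal epithelium lists were called only with the preset correlation, and none of them without WT EtOH replicate 1 (limma adjusted p = 0.379, 0.243 and 0.375). The first also lost its call without WT Dex replicate 2 (limma adjusted p = 0.355) and the second without WT Dex replicate 1 (limma adjusted p = 0.0566). Over both sets (n = 5 per group), edgeR called 843 genes, 487 up and 356 down, with Ccn2 at 4.79 ± 0.046, Sgk1 at 2.54 ± 0.031, Per1 at 3.08 ± 0.076, Hras at 0.35 ± 0.041, Plk2 at -0.85 ± 0.030 and Dusp4 at -0.75 ± 0.038. The count was 1298 without WT EtOH replicate 1 of set 2, and with the replicate number as a block 347 were up and 204 down.

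Between the sets, 3 genes differed in their WT response by edgeR's quasi-likelihood test, against 1173 at an unadjusted p below 0.05 and 31 by DESeq2. Orm3 rose more in set 2 by 1.34 ± 0.192 (SE, n = 3 and 2 per group), as did the vasodilator peptide gene Adm by 0.66 ± 0.080 and Errfi1 by 0.58 ± 0.072. The count was 264 without WT EtOH replicate 1 of set 2 and 5 without either WT Dex replicate of that set. Orm3 was not called without 4 of the libraries in turn, among them WT EtOH replicate 1 of set 1 (1.18). With the length and GC offsets and the replicate block Orm3, Adm and Errfi1 all lost their calls, Orm3 also with the offsets alone and Errfi1 with the block alone. The responses of Ptgs2 (0.38 ± 0.070, adjusted p = 0.133) and Myc (0.20, adjusted p = 0.723) were not called as different by edgeR, though Ptgs2 was without WT EtOH replicate 1 (0.37) or WT Dex replicate 2 (0.45) of set 2.

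**Figure D1:**
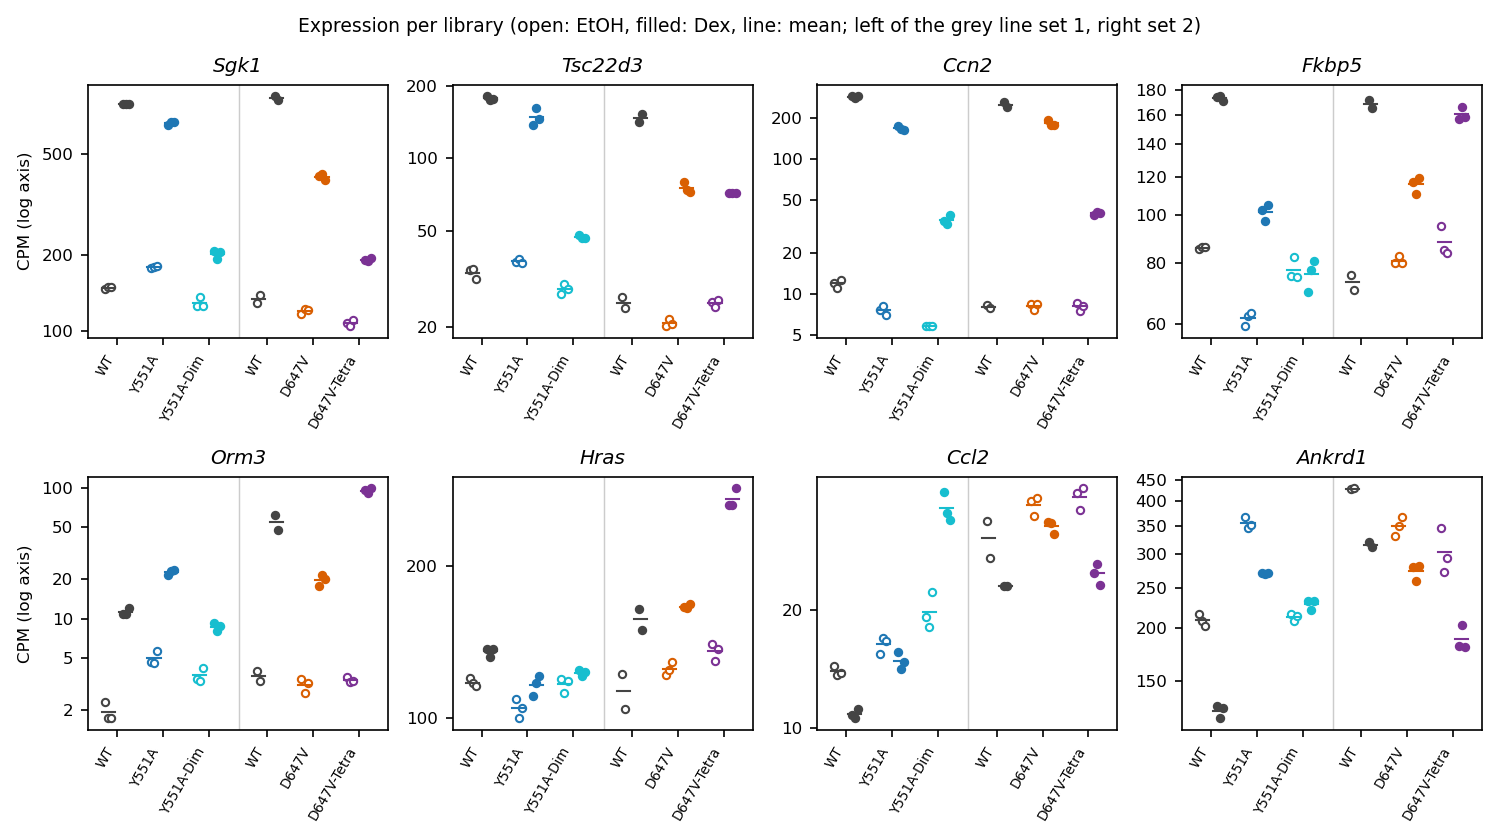
Expression of 8 genes in CPM on log axes, a point per library (open EtOH, filled Dex) and a line at each group mean, with set 1 left and set 2 right of the grey line. Dex levels of Sgk1 averaged 790.4 CPM in WT and 201.5 CPM in Y551A-Dim of set 1, and 836 CPM in WT and 191.5 CPM in D647V-Tetra of set 2.

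Y551A was compared with WT to see how the response of the line with this ligand-binding domain substitution differed. In Y551A (n = 3 per group) Lcn2 rose by 5.71 ± 0.393 (SE), Ccn2 by 4.48 ± 0.060, Fabp4 by 3.35 ± 0.218, Per1 by 2.83 ± 0.127, S100a7a by 2.33 ± 0.216, Orm3 by 2.20 ± 0.099, Tsc22d3 by 1.99 ± 0.051 and Sgk1 by 1.90 ± 0.038. Mt1 (0.88 ± 0.134), Glul (0.73 ± 0.051), Fkbp5 (0.72 ± 0.047), Dusp1 (0.59 ± 0.066), Tgm2 (0.40 ± 0.038) and Cdkn1a (0.31 ± 0.057) also rose. Plau (-0.57 ± 0.069), Phlda1 (-0.55 ± 0.072), the neurotrophin gene Bdnf (-0.51 ± 0.052), Ier3 (-0.45 ± 0.062) and Tmem86a (-0.44 ± 0.088) fell. Ptgs2 (-0.10), Ccl2 (-0.14) and Hras (0.15) were not called. In all, edgeR called 297 genes, 230 up and 67 down. Of the genes up in WT, 193 were also up in Y551A, and 50 were down in both, against 4.6 and 0.9 for independent lists. Classic GR-induced genes rose (24 of 32, 25 adjusted over the list alone, median 0.57), as did 5 of 18 clock genes (6 adjusted over the list alone), and 6 of 21 growth factor feedback genes fell (9 adjusted over the list alone). These calls held with an estimated correlation, at limma's adjusted p of 5.05e-08, 0.0014 and 0.0316.

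Tested as a difference of responses, Y551A fell short of WT for Sgk1 by -0.52 ± 0.052 (SE, adjusted p = 3.92e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Tsc22d3 by -0.42 ± 0.070, the microtubule-associated Map7d2 by -1.08 ± 0.182, the luminal transcription factor Gata3 by -0.96 ± 0.130 and Arl4d by -0.78 ± 0.082. Plk2 (0.49 ± 0.059) and Ptgs2 (0.39 ± 0.071) were repressed less than in WT. Fkbp5 (-0.29, adjusted p = 0.0654) and Per1 (-0.23, adjusted p = 0.901) did not pass edgeR's test. The 29 differing genes comprised 10 with a more positive and 19 with a more negative value in Y551A. Classic GR-induced genes were lower as a list (6 of 32, 13 lower and 2 higher adjusted over the list alone, median -0.21, adjusted p = 0.0317 with an estimated correlation, limma), and growth factor feedback (1 of 21 higher, 5 adjusted over the list alone) and inflammatory genes (1 of 22 higher, 3 adjusted over the list alone) were higher, at 0.0397 and 0.0454. The count was sensitive to single libraries. It was 15 without WT Dex replicate 1 or WT EtOH replicate 3, 17 without WT Dex replicate 3, WT EtOH replicate 2 or Y551A EtOH replicate 2, and 18 without WT EtOH replicate 1, Y551A Dex replicate 2 or Y551A EtOH replicate 1. It was 69 when only these groups were fitted and 62 by DESeq2.

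Y551A-Dim was compared with WT and with Y551A to see how its response differed from each. In it Lcn2 rose by 3.72 ± 0.661 (SE, n = 3 per group), Ccn2 by 2.61 ± 0.063 (from 5.809 ± 0.0295 to 35.32 ± 2.68 CPM, SD), Orm3 by 1.24 ± 0.105, Per1 by 1.22 ± 0.137, Adm by 1.08 ± 0.083, the proteoglycan gene Tsku by 0.95 ± 0.082, Tsc22d3 by 0.72 ± 0.052 and Sgk1 by 0.64 ± 0.037. Fkbp5 (-0.03 ± 0.047, adjusted p = 0.902), Dusp1 (0.10, adjusted p = 0.678), Glul (0.13, adjusted p = 0.301), Mt1 (0.38, adjusted p = 0.186) and Hras (0.08, adjusted p = 0.507) did not pass edgeR's quasi-likelihood test. Mt1 passed it without Y551A-Dim Dex replicate 2 (0.52) or 3 (0.54). The EGF receptor inhibitor Errfi1 (0.76 ± 0.046), the lipase inhibitor Angptl4 (0.67 ± 0.056) and Cdkn1a (0.31 ± 0.059) rose. The chemokines Ccl2 (0.88 ± 0.069, from 19.78 ± 2.1 to 36.29 ± 3.27 CPM, SD) and Ccl7 (0.94 ± 0.096) rose as well. Plk2 (-0.31 ± 0.042) and the inhibitor of differentiation Id3 (-0.33 ± 0.055) fell. Carbonic anhydrase Car9 (2.07 ± 0.355) and the adhesion gene Tenm4 (1.04 ± 0.247) were called, but Tenm4 was not called without Y551A-Dim Dex replicate 1 (0.37). Of the 176 genes called by edgeR, 145 were up and 31 down, and 59 and 18 of these were shared with WT, against 2.9 and 0.4 for independent lists.

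Among groups, 12 of 32 classic GR-induced genes rose and 1 fell in Y551A-Dim (16 and 1 adjusted over the list alone, median 0.13), a call kept with an estimated correlation (adjusted p = 0.000939, limma). Clock genes (4 of 18 up), cholesterol synthesis (2 of 25 down, 20 adjusted over the list alone), cell cycle (1 of 30 down, 24 adjusted over the list alone) and histones (1 of 66 down, 41 down and 1 up adjusted over the list alone) were called with the preset correlation, each at adjusted p = 0.166 with an estimated correlation (limma). The Dex libraries of this line stood apart from each other. Car9 was at 48.4, 15.7 and 7.1 CPM and the haem oxygenase gene Hmox1 at 312, 86 and 38.8 CPM in replicates 1, 2 and 3. The count of called genes was 87 without Dex replicate 1, 297 without Dex replicate 2, 688 without Dex replicate 3, and 89, 116 and 108 without EtOH replicates 1, 2 and 3. It was 45 when only these groups were fitted, 344 by DESeq2, and 281 with length and GC offsets.

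**Figure D2:**
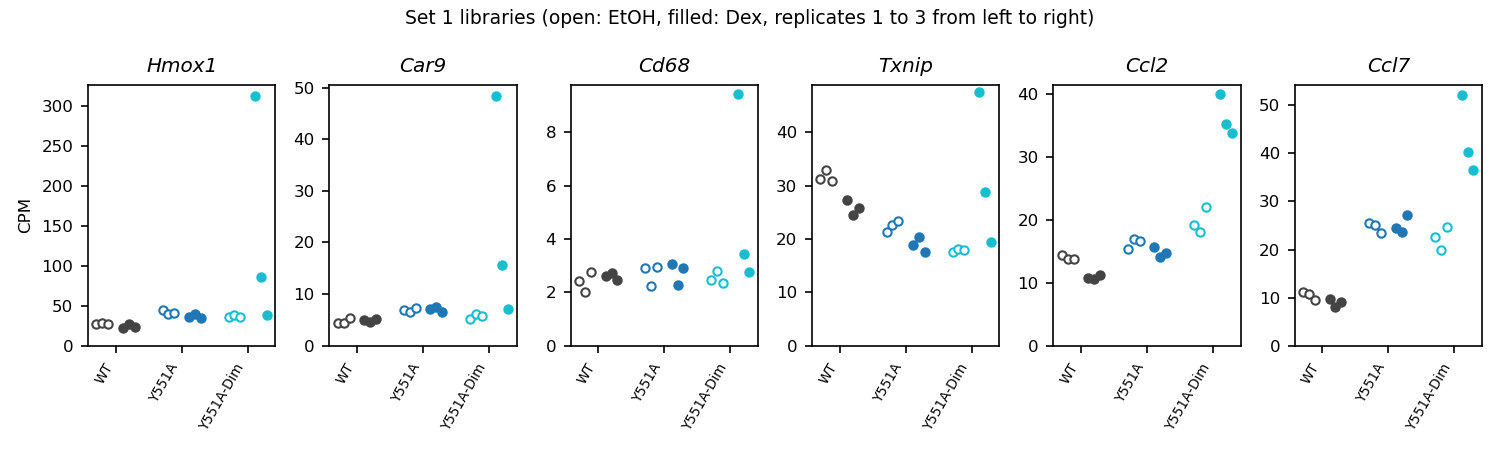
Expression in CPM of 6 genes in every library of set 1 (open EtOH, filled Dex, replicates 1 to 3 from left to right). Hmox1 was at 312 CPM in Y551A-Dim Dex replicate 1 and at 38.8 CPM in replicate 3.

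The difference between Y551A-Dim and WT was tested directly in edgeR (n = 3 per group). The response was smaller in Y551A-Dim for S100a7a (-3.11 ± 0.253, SE), Spsb1 (-2.27 ± 0.114), the arrestin-domain gene Arrdc2 (-2.17 ± 0.130), Per1 (-1.84 ± 0.190), Sgk1 (-1.77 ± 0.052, adjusted p = 1.91e-18 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Tsc22d3 (-1.69 ± 0.072) and Fkbp5 (-1.04 ± 0.066). Fabp4 (-2.55), Map7d2 (-2.00), Mt1 (-0.89), Dusp1 (-0.86), Glul (-0.72) and Tgm2 (-0.37) differed the same way, and Lcn2 (-1.64 ± 1.2) was not called, with 0.3389 CPM in Dex and 0.02363 CPM in EtOH in Y551A-Dim. In the other direction, Ccl2 differed by 1.24 ± 0.104, since it rose in Y551A-Dim and fell in WT, and Ccl7 by 1.17 ± 0.149, the thioredoxin-binding Txnip by 1.12 ± 0.230, Ankrd1 by 0.81 ± 0.052 and Myc by 0.37 ± 0.078. Txnip was at 47.5, 28.8 and 19.4 CPM in Y551A-Dim Dex replicates 1, 2 and 3 against a mean of 18 CPM in EtOH, so its rise was uneven between libraries. Nr3c1 responses differed by 0.26 ± 0.043. Hmox1 (2.16 ± 0.540) was called as well, and lost its call when any of 9 libraries was left out, among them WT Dex replicate 1 (2.104). Of 238 called genes, 95 had a more positive and 143 a more negative value than in WT. Classic GR-induced genes were lower (19 of 32 lower and 2 higher, 22 and 2 adjusted over the list alone, median -0.62). Growth factor feedback (7 of 21 higher, 11 adjusted over the list alone) and inflammatory genes (4 of 22 higher, 7 higher and 1 lower adjusted over the list alone) were higher. With an estimated correlation limma gave adjusted p = 2.13e-06, 0.0033 and 0.00783. Immediate early genes were higher (5 of 24, 10 adjusted over the list alone) with adjusted p = 0.0541 with an estimated correlation (limma). Among members of these lists, Phlda1 (0.69), Ier3 (0.69), Hbegf (0.62), Dusp4 (0.60) and Irf1 (0.45) were less repressed.

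Against Y551A, 90 genes differed by edgeR, 16 with a more positive and 74 with a more negative value (n = 3 per group). Ccn2 was lower by -1.87 ± 0.089 (SE), Tsc22d3 by -1.27 ± 0.072, Sgk1 by -1.25 ± 0.052 and Fkbp5 by -0.75 ± 0.067, along with S100a7a (-2.95), Fabp4 (-2.87), Per1 (-1.61), Spsb1 (-1.61) and Glul (-0.61). Ccl2 (1.02 ± 0.102), Ccl7 (0.92 ± 0.138) and Tcim (0.66 ± 0.098) were higher. Of 32 classic GR-induced genes 16 were lower and none higher (22 and 2 adjusted over the list alone, median -0.44, adjusted p = 1.83e-05 with an estimated correlation, limma). The immune cell marker list was called higher without a member passing over all genes (4 of 6 adjusted over the list alone, median 0.69, adjusted p = 0.0649 with an estimated correlation, limma), and its members did not all follow the Dex library that stood apart in Hmox1. In replicates 1, 2 and 3 the macrophage marker Cd68 was at 9.43, 3.43 and 2.75 CPM, Lyz2 at 6.61, 6.6 and 6.43 CPM and Cd14 at 9.17, 8.44 and 9.09 CPM. The count was 225 without Y551A-Dim Dex replicate 3 and 153 by DESeq2.

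D647V was compared with the WT of set 2 to ask the same of the line with the other ligand-binding domain substitution. Lcn2 rose by 5.55 ± 0.353 (SE, n = 3 per group), Ccn2 by 4.49 ± 0.064, Per1 by 2.82 ± 0.139, Orm3 by 2.66 ± 0.113, Fabp4 by 2.13 ± 0.194, Tsc22d3 by 1.86 ± 0.055 and Sgk1 by 1.76 ± 0.044. Mt1 (0.71 ± 0.061), Dusp1 (0.57 ± 0.091), Fkbp5 (0.52 ± 0.052), Cdkn1a (0.50 ± 0.086), Glul (0.45 ± 0.041), Hras (0.41 ± 0.059) and Tgm2 (0.33 ± 0.060) rose less. Plk2 (-0.53 ± 0.050), Bdnf (-0.49 ± 0.065), the xenobiotic receptor gene Ahr (-0.46 ± 0.068), Gadd45a (-0.44 ± 0.070) and Ptgs2 (-0.41 ± 0.051) fell, while Ccl2 (-0.18, adjusted p = 0.575) did not pass edgeR's test. edgeR called 165 genes, 141 up and 24 down, and shared 128 and 21 with WT, against 1.9 and 0.1 for independent lists. Classic GR-induced genes rose (21 of 32, 22 up and 1 down adjusted over the list alone, median 0.48), and 4 of 22 growth factor feedback genes fell (10 down and 1 up adjusted over the list alone). Mitochondrially encoded genes were called up (2 of 14, 6 adjusted over the list alone, median 0.34). With an estimated correlation limma gave adjusted p = 1.17e-06, 0.0295 and 0.0307 for these lists.

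The response of D647V was smaller than that of WT for Errfi1 (-1.15 ± 0.103, SE, adjusted p = 3.46e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 against 2 per group), Arrdc2 (-1.11 ± 0.104), Arl4d (-1.05 ± 0.119), Spsb1 (-0.97 ± 0.131), Sgk1 (-0.88 ± 0.068), Mt1 (-0.87 ± 0.096), Fkbp5 (-0.69 ± 0.082), Tsc22d3 (-0.69 ± 0.084) and Glul (-0.53 ± 0.064). Of the 33 genes called, 32 were lower and 1, Dusp4 (0.47), higher, and Dusp4 lost its call when any of 7 libraries was left out, among them WT EtOH replicate 1 (0.45). Classic GR-induced genes were lower (9 of 32, 17 adjusted over the list alone, median -0.38, adjusted p = 0.000424 with an estimated correlation, limma). The count was 21 without WT Dex replicate 1, 19 without D647V EtOH replicate 2, 64 by DESeq2, 56 with all 34 libraries in 1 fit, and 59 with the length and GC offsets.

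D647V-Tetra was compared with WT and with D647V to see how its response differed from each. In D647V-Tetra (n = 3 per group) Lcn2 rose by 6.56 ± 0.345 (SE), Orm3 by 4.82 ± 0.115 (from 3.393 ± 0.17 to 95.54 ± 4.24 CPM, SD), Per1 by 2.74 ± 0.143, Spsb1 by 2.50 ± 0.087, Fabp4 by 2.30 ± 0.193 and Ccn2 by 2.29 ± 0.061. Tsc22d3 (1.51 ± 0.054), Dusp1 (1.33 ± 0.093), Tgm2 (1.12 ± 0.061), Hras (1.01 ± 0.059, from 135.5 ± 5.14 to 271.9 ± 12.1 CPM, SD), Mt1 (0.93 ± 0.061), Fkbp5 (0.87 ± 0.052), Sgk1 (0.84 ± 0.043), Glul (0.72 ± 0.041) and Cdkn1a (0.66 ± 0.086) also rose. Plk2 (-0.94 ± 0.050), the chemokine Cxcl5 (-0.93 ± 0.131), Clec2d (-0.90 ± 0.118), Ccl2 (-0.65 ± 0.075) and Ptgs2 (-0.45 ± 0.051) fell. By edgeR 3367 genes were called, 1984 up and 1383 down (716 and 91 at least 1.5-fold), but with all 34 libraries in 1 fit 2192 were up and 2669 down, and with the axis covariate 584 up and 146 down. As reported, the up and down lists overlapped those of WT, with 183 and 50 shared with WT of set 2, against 26.7 and 5.2 for independent lists. Of the 3367 genes, 328 (260 up and 68 down) were called in all 5 of the fits as reported, with the length and GC offsets, with these offsets and the replicate block, with the within-group axis as a covariate, and without EtOH replicates 1 and 3.

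Properties of the libraries moved with this count. The slope of log2 CPM on transcript length was -0.1029, -0.0386 and -0.0807 in D647V-Tetra EtOH replicates 1 to 3 and 0.0539, 0.0156 and 0.0588 in its Dex replicates. Replication-dependent histones fell (51 of 66, 57 adjusted over the list alone, adjusted p = 0.185 with an estimated correlation, limma), with Hist1h1c at -0.36. Ribosomal protein genes fell (28 of 33, 32 adjusted over the list alone, adjusted p = 0.305 with an estimated correlation, limma), with Rps14 at -0.31, as did 6 of 18 structural non-coding RNAs (7 adjusted over the list alone, adjusted p = 0.287 with an estimated correlation, limma). The small RNAs Snora23 (-1.43 ± 0.440, SE) and Rny1 (-1.17 ± 0.363), which the naming rule took, lost their calls without EtOH replicate 1 (-1.03 and -0.84) or 3 (-1.49 and -1.20), or Dex replicate 1 (-1.39 and -1.37) or 3 (-1.13 and -0.87). Classic GR-induced genes rose (24 of 32 up and 3 down, 25 and 3 adjusted over the list alone, median 0.69, adjusted p = 3.43e-05 with an estimated correlation, limma). Inflammatory genes (9 of 22 down and 2 up, 10 and 2 adjusted over the list alone) and the integrated stress response (9 of 19 down, 10 adjusted over the list alone) were called down, both at adjusted p = 0.09 with an estimated correlation (limma). The list of GR chaperones and cofactors was called up (11 of 26 up and 1 down, 12 and 6 adjusted over the list alone) at adjusted p = 0.09 with an estimated correlation (limma). Its members did not move together. Against the response of WT, the chaperone gene Dnaja1 was lower (-0.522) and the cofactor gene Ep300 higher (1.023). The count of called genes was 1916 and 1699 without EtOH replicates 1 and 3, 1635 and 1346 without Dex replicates 1 and 3. Without both EtOH replicates 1 and 3 it was 377, with the axis covariate 730, and 1998 with the offsets and the replicate block.

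**Figure D3:**
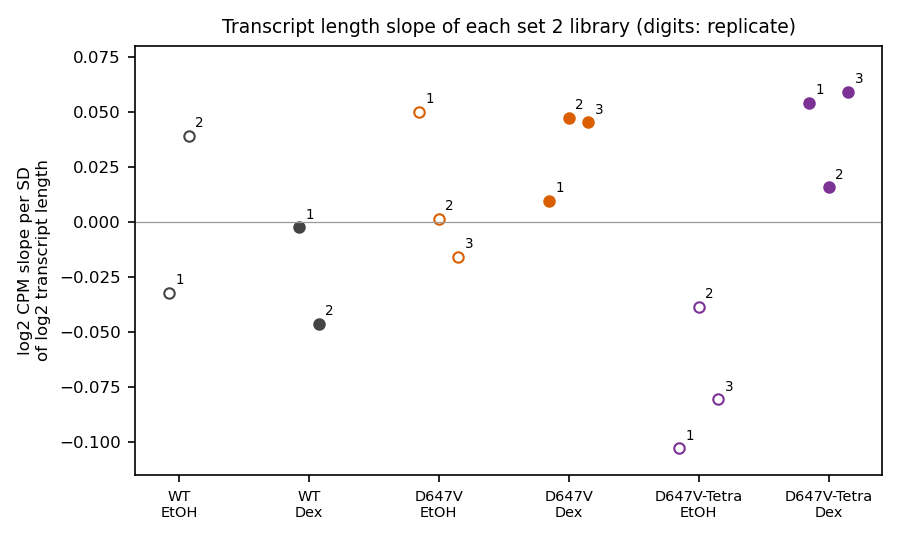
Slope of log2 CPM on transcript length for each library of set 2, per SD of log2 length, with the replicate number beside each point (open EtOH, filled Dex). D647V-Tetra EtOH replicate 1 had the lowest slope (-0.1029) and D647V-Tetra Dex replicate 3 the highest (0.0588).

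In the difference from WT, Ccn2 responded less in D647V-Tetra by -2.68 ± 0.096 (SE, adjusted p = 3.1e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 against 2 per group), S100a7a by -2.36 ± 0.315, Sgk1 by -1.81 ± 0.068, Cxcl5 by -1.46 ± 0.204, Arrdc2 by -1.17 ± 0.104, Tsc22d3 by -1.04 ± 0.084 and Mt1 by -0.65 ± 0.096. Hras responded more, by 0.53 ± 0.093, and was not called without WT Dex replicate 2 (0.46). Ptgs2 fell more than in WT (-0.36 ± 0.081, adjusted p = 0.0208 by edgeR) and lost its call without WT EtOH replicate 2 (-0.37), WT Dex replicate 1 (-0.28), or D647V-Tetra Dex replicate 1 (-0.33) or 3 (-0.36). Under the naming rule, with an average log2 CPM of at least 1, the highest differences were in Hivep3 (1.36), the neuron navigator Nav2 (1.33), the histone methyltransferase Kmt2d (1.31), Cacng7 (1.24), the RNA polymerase subunit Polr2a (1.21) and Zbtb20 (1.20). Of these, Hivep3, Nav2, Kmt2d and Cacng7 lost their calls without WT EtOH replicate 2 (1.28, 1.12, 1.21 and 1.24) or WT Dex replicate 2 (1.295, 1.15, 1.21 and 1.1), and Cacng7 without 3 more libraries. All of the genes from Hivep3 to Zbtb20 lost their calls without both D647V-Tetra EtOH replicates 1 and 3. That fit kept a single EtOH library of this line, so a lost call does not show that the difference went away. Of 774 genes called, 649 were higher and 125 lower, and 32 (10 higher, 22 lower) were called in all 5 fits. Classic GR-induced genes were lower (10 of 32 lower and 1 higher, 14 and 2 adjusted over the list alone, median -0.26, adjusted p = 0.0896 with an estimated correlation, limma). Ribosomal protein genes were called lower with no member passing over all genes (21 of 33 adjusted over the list alone, adjusted p = 0.568 with an estimated correlation, limma). The count was 1617, 81 and 95 without WT EtOH replicate 1, WT EtOH replicate 2 and WT Dex replicate 2. It was 453, 1634 and 338 without D647V-Tetra EtOH replicates 1, 2 and 3, and 337, 1541 and 361 without its Dex replicates. It was 34 without both EtOH replicates 1 and 3, 81 with the axis covariate, 1774 by DESeq2, 2624 with all 34 libraries in 1 fit, and with the length and GC offsets 383 were higher and 219 lower.

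Against D647V, Orm3 responded more in D647V-Tetra by 2.15 ± 0.159 (SE, adjusted p = 1.21e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per group), and the magnesium transporter family gene Nipal1 by 1.63 ± 0.171. The adhesion receptor Adgra1 responded more by 1.28 ± 0.127, the interleukin receptor subunit Il6ra by 1.11 ± 0.114, the mitochondrial carrier Slc25a33 by 1.02 ± 0.149, the salt-inducible kinase Sik1 by 0.97 ± 0.129, Tgm2 by 0.79 ± 0.085 and Hras by 0.60 ± 0.083. Ccn2 (-2.20 ± 0.085) and Sgk1 (-0.93 ± 0.061) responded less. Tsc22d3 (-0.35) was called lower and lost its call when any of 10 libraries was left out, among them D647V EtOH replicate 1 (-0.33). Of 153 genes, 136 were higher and 17 lower, and 27 (25 higher, 2 lower) were called in all 5 fits. Classic GR-induced genes were called higher (6 of 32 higher and 2 lower, 10 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.494 with an estimated correlation, limma). The count was 55, 49 and 251 without D647V EtOH replicates 1, 2 and 3, 71, 65 and 65 without its Dex replicates. It was 66, 271 and 64 without D647V-Tetra EtOH replicates, and 69 and 53 without its Dex replicates 1 and 3. It was 29 without both EtOH replicates 1 and 3, 82 with the replicate block, 493 by DESeq2 and 495 with all 34 libraries in 1 fit.

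To compare all lines on genes not chosen in their own set, lists were taken from the WT response of the other set. For these lists the WT libraries of a set were fitted alone. Their sizes therefore differ from the 1.5-fold counts of the fits with all lines of a set. The 114 genes induced at least 1.5-fold in WT of set 2 had a median of 0.97 in WT of set 1, 0.73 in Y551A and 0.20 in Y551A-Dim, with 108, 97 and 31 called up by edgeR. The 150 genes induced in WT of set 1 had a median of 0.98 in WT of set 2, 0.63 in D647V and 1.12 in D647V-Tetra, with 89 called up in D647V and 126 in D647V-Tetra. The median difference from WT was -0.26 in Y551A (18 lower, adjusted p = 2.29e-07 by limma's fry), -0.79 in Y551A-Dim (85 lower, adjusted p = 7.99e-13), and -0.35 in D647V (28 lower, adjusted p = 0.00036), with no gene higher in any of these. D647V-Tetra differed in both directions, with 10 higher and 27 lower genes, or 2 higher and 20 lower with the axis covariate. Without that covariate the median was -0.03 (adjusted p = 0.0712 by limma's fry), with adjusted p = 2.1e-10 by fry for change in either direction. The unadjusted p fell below 0.05 without WT Dex replicate 2 of set 2 (median -0.05) or D647V-Tetra EtOH replicate 1 (median -0.08), and the median was 0.04 without WT Dex replicate 1 of set 2. Against D647V, D647V-Tetra was higher (median 0.34, 24 higher and 7 lower, adjusted p = 0.00308 by limma's fry), and against Y551A, Y551A-Dim was lower (median -0.52, 56 lower, adjusted p = 4.42e-11). The fry tests of D647V-Tetra were not repeated with the axis covariate or with its EtOH libraries left out in pairs. Whether its higher value against D647V depends on that axis or those libraries was therefore not tested. Repressed genes were fewer, 17 in set 1 and 19 in set 2. Their medians were -0.55, -0.37 and -0.13 in WT, Y551A and Y551A-Dim, and -0.60, -0.36 and -0.39 in WT, D647V and D647V-Tetra. The difference from WT was 0.18 in Y551A, 0.42 in Y551A-Dim and 0.18 in D647V, at adjusted p = 3.02e-06, adjusted p = 8.16e-10 and adjusted p = 0.00036 by limma's fry, and 0.02 in D647V-Tetra (adjusted p = 0.124).

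**Figure D4:**
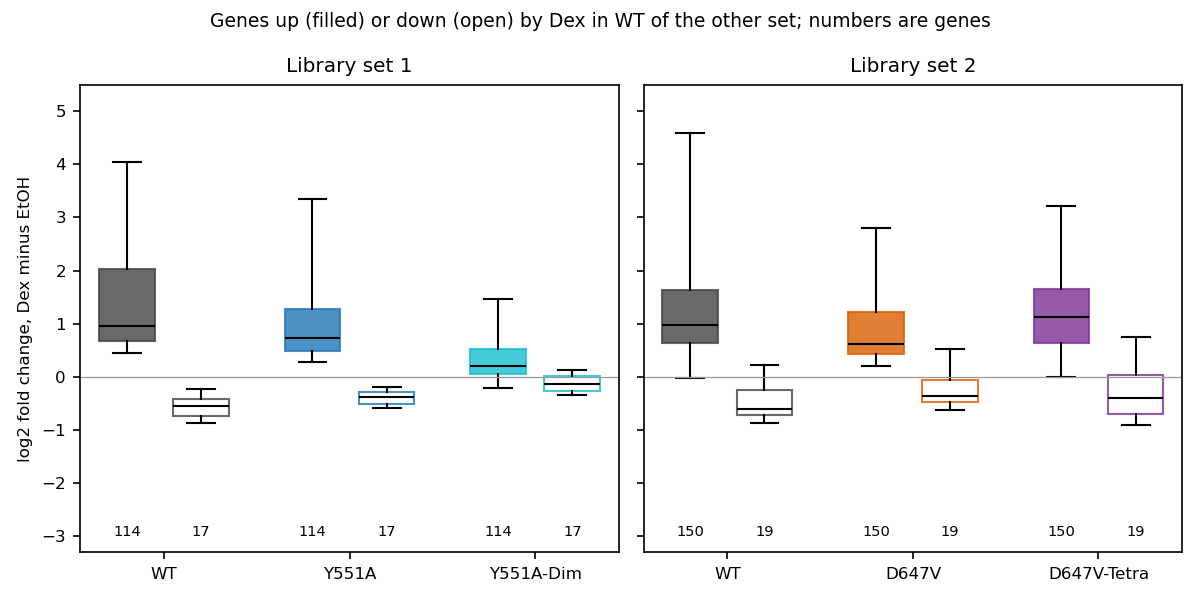
Log2 fold changes (Dex minus EtOH) of genes that rose (filled) or fell (open) at least 1.5-fold in WT of the other set, as boxes of median and quartiles, with gene numbers below. The induced genes had a median of 0.20 in Y551A-Dim against 0.97 in WT of set 1, and of 1.12 in D647V-Tetra against 0.98 in WT of set 2. Gene by gene, the difference of D647V-Tetra from WT had a median of -0.029, with 10 genes called higher and 27 lower.

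Baselines in EtOH were compared to see how the lines differed before Dex. Y551A cells differed widely from WT (n = 3 per group): the mast cell tryptase gene Tpsab1 (4.39 ± 0.117, SE), the cytoskeletal adducin Add2 (3.90 ± 0.209) and the keratins Krt16 (3.86 ± 0.189) and Krt14 (2.48 ± 0.081) were higher, and matrix Gla protein Mgp (-3.83 ± 0.119) was lower. Pcolce2 (2.81) and Acsbg1 (2.32) were higher, and Tenm4 (-3.74), the collagen Col11a1 (-2.75), Fabp4 (-2.72) and Adgrl2 (-2.54) lower. Among glucocorticoid targets, Cdkn1a (0.98 ± 0.059) and Dusp1 (0.87) were higher and Fkbp5 (-0.48 ± 0.047) lower before treatment. Integrated stress response genes were lower (15 of 18, median -0.66, adjusted p = 0.000807 with an estimated correlation, limma), including the pseudokinase Trib3 (-1.15 ± 0.051), Chac1 (-1.03 ± 0.053) and the transcription factor Atf4 (-0.67 ± 0.038). Of 30 cell cycle genes, 27 were lower and 1 higher (28 and 1 adjusted over the list alone), including the replication genes Cdc6 (-1.09) and Mcm7 (-0.85), at adjusted p = 0.11 with an estimated correlation (limma). edgeR called 6855 genes, 3057 higher and 3798 lower, and at least 1.5-fold 934 were higher and 554 lower. The length slopes of the EtOH libraries were 0.0152 to 0.0315 in Y551A and -0.0367 to -0.0191 in WT.

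Y551A-Dim was compared at baseline with the same 3 WT EtOH libraries (n = 3 per group), so agreement between these comparisons is expected in part. Krt16 (2.54 ± 0.197, SE), Add2 (2.16), Tpsab1 (2.01), Pcolce2 (1.84), the glutathione transferase Gsta2 (1.64) and Serpinb1a (1.47) were higher, and Mgp (-3.24), Lcn2 (-2.98, at 0.02363 ± 0.0205 against 0.2059 ± 0.0725 CPM, SD), Tenm4 (-2.45) and Col11a1 (-1.69) lower. Ccl2 was higher (0.50) and Cxcl1 lower (-0.68) before Dex. Integrated stress response genes were lower (15 of 18, median -0.43, adjusted p = 0.000715 with an estimated correlation, limma), including Chac1 (-0.64), Trib3 (-0.55) and Atf5 (-0.49). edgeR called 3757 genes, 1617 higher and 2140 lower, and at least 1.5-fold 556 were higher and 210 lower.

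In set 2, the hyaluronan-linking Hapln1, the integrin Itgb2, the lectin receptor Clec1a and Ssu2 were higher at baseline in D647V (1.299, 1.00, 1.32 and 1.53) and in D647V-Tetra (1.40, 1.12, 1.37 and 1.26) than in WT (n = 3 against 2). Tpsab1 was lower by -2.67 ± 0.115 (SE) and -3.14 ± 0.118, the endothelial cadherin Cdh5 by -1.46 and -1.54, the Wnt modulator Sfrp2 by -1.34 and -1.55, and the Z-disc gene Ldb3 by -1.33 and -2.04. S100a7a was higher in D647V-Tetra (1.5 ± 0.244) and in D647V (1.24), where it was not called without WT EtOH replicate 1 (0.85). Agreement between the lines is expected in part, since both were compared with the same 2 WT EtOH libraries. Cell cycle genes were higher in each (27 of 30 each, 29 and 28 adjusted over the list alone), with Mcm6 at 0.38 in D647V and 0.498 in D647V-Tetra and adjusted p = 0.0391 and 0.0289 with an estimated correlation (limma). Integrated stress response genes were higher (9 and 10 of 19, 11 and 11 adjusted over the list alone), at adjusted p = 0.0504 and 0.0289 with an estimated correlation (limma). Basal epithelial markers were lower (3 and 4 of 7), including Krt14 (-1.19 and -0.96) and Itga6 (-0.53 and -0.69), as were YAP and TGF-beta targets in D647V-Tetra (16 of 23 lower and 1 higher, median -0.26, adjusted p = 0.0143 with an estimated correlation, limma), including Tgfb2 (-0.79). The EtOH libraries of D647V-Tetra compared here had lower length slopes, from -0.1029 to -0.0386, than the other EtOH libraries of set 2. edgeR called 1290 genes for D647V, 803 higher and 487 lower, and 3277 for D647V-Tetra, 1640 higher and 1637 lower. At least 1.5-fold, 83 were higher and 159 lower for D647V, and 142 and 490 for D647V-Tetra. For D647V the count was 387 without WT EtOH replicate 1, 645 and 725 without D647V EtOH replicates 2 and 3, 741 with only these groups fitted, 2057 with the offsets and 2517 with the axis covariate. For D647V-Tetra it was 1554 without WT EtOH replicate 2, 1894 with only these groups fitted and 968 without both EtOH replicates 1 and 3.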

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

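The tests with the length and GC offsets on the count of D647V-Tetra, those that left out pairs of EtOH libraries for that count, the sum of macrophage transcripts, the axis covariate for the genes induced in WT, and the exchange of treatments within lines were chosen only after the results were seen. So were the hypoxia, NRF2 and macrophage lists, which were drawn up once Hmox1, Car9, Adm and Cd68 had been seen per library, and the criterion for the spread of the axis covariate, which was added once its value was known.

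Each of the following differs between lines by a test of the difference itself, edgeR's quasi-likelihood test of the interaction. The labels give a single line per receptor form, so its effect cannot be told apart from other differences between the lines. Y551A and WT differed in 29 genes, Y551A-Dim and WT in 238, Y551A-Dim and Y551A in 90, D647V and WT in 33, D647V-Tetra and WT in 774, and D647V-Tetra and D647V in 153. When line labels were exchanged among the libraries, 9 of 50 splits called as many genes as the real one in each of the 3 comparisons of set 1 and 4 of 50 in D647V-Tetra against D647V. The highest counts of other splits were 8479, 6184, 6325 and 1230, several times the real ones, which points to a structure of the samples, since exchanging line labels puts the baseline differences between lines into the contrast. When treatments were exchanged within lines instead, 3, 3, 4 and 4 of 50 splits called as many, with highest counts of 693, 627, 373 and 2539, but these splits bring the Dex response itself into the contrast. Neither kind of split therefore shows whether chance can be excluded. Tests that do not rest on them were those of single genes, such as Sgk1 in Y551A-Dim minus WT (-1.773 ± 0.052, adjusted p = 1.91e-18, edgeR), and of the 114 genes chosen in the other set, of which 85 were lower in Y551A-Dim than in WT and none higher.

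In 4 genes the response was called in both lines and ran in opposite directions, of which Gdnf, Slc31a2 and Plpp1 were chosen after their values were seen. Ccl2 rose by 0.875 ± 0.069 (SE) in Y551A-Dim and fell by 0.365 ± 0.077 in WT, a difference of 1.239 ± 0.104 (adjusted p = 4.1e-09, edgeR, n = 3 per group). The neurotrophic factor gene Gdnf rose by 0.308 and fell by 0.315 in the same lines, a difference of 0.624 ± 0.093 (adjusted p = 9.76e-05, edgeR). The copper transport gene Slc31a2 fell by 0.257 ± 0.047 in D647V-Tetra and rose by 0.448 in WT, a difference of -0.705 ± 0.073 (adjusted p = 6.3e-05, edgeR). The lipid phosphatase gene Plpp1 fell by 0.198 ± 0.053 and rose by 0.291, a difference of -0.489 ± 0.084 (adjusted p = 0.00523, edgeR). Both decreases in D647V-Tetra are from the fit as reported. Whether they hold with the axis covariate or without its EtOH replicates 1 and 3 is not given here.

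The broad Dex response of D647V-Tetra, 3367 genes against 302 in WT of set 2, went with a slope on transcript length that differed between its EtOH and Dex libraries. Offsets over length and GC left 2697 genes called, 1855 of them among the genes called before, which argues against that trend as the whole source. Leaving out EtOH replicates 1 and 3, which lie at the end of the axis of within-group variation among the libraries of their line, left 377, whereas leaving out replicates 1 and 2 left 1297 and replicates 2 and 3 left 3603, so these libraries may carry much of the count, as a hypothesis found on the same data. With the axis as a covariate 730 were called, between 440 and 1007 when a further library was left out, on both sides of the bound of 604 set for it. That bound rested on the 302 genes of WT in the fit without the covariate. With the covariate WT of set 2 had 405, so a bound from that fit would be higher, and 730 lies under 2 times 405. Across 10296 genes the Dex change of D647V-Tetra followed the axis (Spearman rho 0.685). The rho was 0.338 in D647V and -0.368 in WT of set 2, so the comparison with WT also involves the axis. The axis cannot be told apart from the treatment because each Dex library of D647V-Tetra scored higher on it (-0.51 to 8.09) than each EtOH library of that line (-13.87 to -3.7). A broader response of this receptor form stays open.

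In some Y551A-Dim Dex libraries Hmox1 and Car9 were higher than in EtOH, by 3.09 log2 each in replicate 1, 1.23 and 1.47 in replicate 2, and 0.085 and 0.338 in replicate 3. Macrophages in the culture would bring their abundant transcripts along, but 5 of these together rose by 0.349 CPM between replicates 3 and 1 while Cd68 rose by 6.69 CPM, which argues against them, and the median of 0.219 rested on only 2 measurable members. Targets of the oxidative stress factor NRF2 rose by a median of 0.156 in replicate 1, far less than Hmox1, although this was at the 99.97 percentile of random lists. Its members were uneven. In replicate 1 Gclm was at 106 CPM against an EtOH mean of 65.8 and Nqo1 at 167 against 116. Gsr (188 against 189) and Osgin1 (6.75 against 6.89) did not rise, so the median does not exclude oxidative stress. The 12 hypoxia targets had a median of 0.342 in replicate 1, against 0.043 and 0.014 in replicates 2 and 3, so low oxygen in that culture is a candidate explanation for Car9 in replicate 1, on a list chosen after Car9 was seen. A role of the receptor form in this pattern was not tested.

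Of genes induced in WT of set 1, 10 responded more and 27 less in D647V-Tetra than in WT of set 2. With the length and GC offsets 9 were higher and 25 lower, which argues against that trend as the source. Without EtOH replicates 1 and 3, 2 were higher and 17 lower, and with the axis covariate and all libraries kept 2 were higher and 20 lower, so the higher side may depend on these libraries or on that axis. The median of the 10 higher genes was 0.637 (median SE 0.144) as reported, 0.532 (0.146) without both libraries and 0.47 (0.153) with the axis covariate, although these genes were picked as higher on the same data. Without both libraries the calls ended with a smaller difference in Il6ra (0.628 ± 0.129 before, 0.431 ± 0.104 after) and with a larger SE in Orm3 (0.92 ± 0.175 before, 0.966 ± 0.229 after), 2 genes singled out after their values were seen. Nipal1 (1.43 ± 0.217) and Adgra1 (1.19 ± 0.150) were called without both libraries, as they were with the axis covariate (1.323 ± 0.233 and 0.945 ± 0.164), and a gene-specific gain of response in this receptor form stays open as a hypothesis.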

How the results depend on the processing

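The length and GC offsets, alone or with the replicate block, the axis covariate, leaving out D647V-Tetra EtOH replicates 1 and 3, and repeating the list tests in these fits were tests chosen after the data had been seen. Scaling by spike-in reads was not run. Where a value changed, the cause was not tested, except that leaving out libraries, blocks and smaller fits remove degrees of freedom.

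Of 374 named gene results that were called, 285 were called in every setting and with every library left out, 89 lost the call somewhere, and 1 turned: Snora23 in D647V-Tetra was 0.039 with the axis covariate. Of 136 not called, 38 were called somewhere. Of 298 values of gene counts under an alternative, 199 stayed within 1.5 times. An estimated correlation left 51 of 174 list calls, and the ribosomal protein list for WT set 2 minus WT set 1 turned without WT EtOH (adjusted p = 0.143, limma) or Dex replicate 2 of set 2 (adjusted p = 0.386, limma), and had its lowest adjusted p, 1.7e-08, without WT EtOH replicate 1 of set 2 (limma). Nr3c1 kept its direction and calls with DESeq2 size factors, which moved no count by over 1.5 times.

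With only the groups compared, 848 genes were called for WT in set 1, 45 for Y551A-Dim, 69 for Y551A minus WT, 464 for D647V-Tetra minus WT, and 741 and 1894 for the D647V and D647V-Tetra baselines. Without a low-count filter there were 491 for Y551A-Dim, 583 for WT in set 2, 380 for D647V, and, for differences, 156 (WT set 2 minus set 1), 109 (Y551A minus WT), 422 (Y551A-Dim minus WT), 250 (Y551A-Dim minus Y551A), 244 (D647V minus WT), 2424 (D647V-Tetra minus WT) and 936 (D647V-Tetra minus D647V). DESeq2 called 344 for Y551A-Dim, and for the same differences except Y551A-Dim minus WT 31, 62, 153, 64, 1774 and 493. The replicate block gave 5.5e+02 for WT over both sets, 431 for D647V-Tetra minus WT and 82 for D647V-Tetra minus D647V. All 34 libraries in 1 fit gave 56 for D647V minus WT, 2624 for D647V-Tetra minus WT (1348 higher, 1276 lower) and 495 for D647V-Tetra minus D647V, and 2192 up and 2669 down for D647V-Tetra itself.

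The offsets gave 281 for Y551A-Dim (204 up, 77 down), 5 for WT set 2 minus set 1, 45 for Y551A minus WT, 59 for D647V minus WT and 2057 for the D647V baseline. With the block they gave 302 for Y551A-Dim (208 up, 94 down), 1998 for D647V-Tetra, 44 for Y551A minus WT, 298 for D647V-Tetra minus WT and 90 for D647V-Tetra minus D647V. For WT set 2 minus set 1, edgeR then called 0, against 31 by DESeq2 and 1173 at an unadjusted p below 0.05 without the offsets. The axis covariate gave 259 for D647V, 730 for D647V-Tetra, 59 for D647V minus WT, 81 for D647V-Tetra minus WT and 2517 for the D647V baseline. Without EtOH replicates 1 and 3, 377 were called for D647V-Tetra, 34 minus WT, 29 minus D647V and 968 at baseline.

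Transfer lists of repressed genes with a minimum of 2-fold held 1 gene in set 1 and 6 in set 2, and gave -0.892 for Y551A minus WT, -0.226 and 0.666 for Y551A-Dim minus WT and minus Y551A, 0.339 for D647V minus WT and 0.237 for D647V-Tetra minus D647V, none past the threshold. With no minimum the last was -0.074. For induced genes in D647V-Tetra minus WT, the difference passed with a minimum of 2-fold (-0.269), DESeq2 size factors (-0.037), offsets (-0.035), and without WT Dex replicate 2 (-0.048) or D647V-Tetra EtOH replicate 1 (-0.075), the lowest value with a library left out, and not without WT Dex replicate 1, the highest (0.04). For repressed genes it passed with the offsets (0.105).

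With each library left out, counts ranged from 409 to 487 for WT in set 1, 233 to 303 for Y551A, 87 (Dex 1 out) to 688 (Dex 3 out) for Y551A-Dim, 200 (Dex 1 out) to 233 for WT in set 2, 121 to 185 for D647V, 1346 (Dex 3 out) to 4019 (EtOH 2 out) for D647V-Tetra and 661 to 1298 (WT EtOH 1 of set 2 out) for WT over both. For differences they ranged from 2 to 264 (WT EtOH 1 of set 2 out) between WT sets, 15 (WT Dex 1 out) to 31 for Y551A minus WT, 192 to 337 and 70 to 225 (Dex 3 out) for Y551A-Dim minus WT and minus Y551A, 19 (D647V EtOH 2 out) to 35 for D647V minus WT, and 81 (WT EtOH 2 out) to 1634 (EtOH 2 out) and 49 (D647V EtOH 2 out) to 271 (EtOH 2 out) for D647V-Tetra minus WT and minus D647V. Baselines ranged from 6037 to 6246 for Y551A, 2535 to 3400 for Y551A-Dim, 387 (WT EtOH 1 out) to 1057 for D647V and 1554 (WT EtOH 2 out) to 3595 for D647V-Tetra.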

Other observations

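The chance splits in this part were fixed before the data were examined. Beyond the lists named so far, the EtOH baselines differed in several gene groups. In Y551A, 14 of 24 extracellular matrix genes were higher than in WT and 2 lower, including the collagens Col6a1 (1.54) and Col6a2 (1.58) and the matricellular Postn (1.43), at adjusted p = 0.0917 with an estimated correlation (limma). Of 19 p53 targets 11 were higher and 3 lower (12 and 3 adjusted over the list alone), also at adjusted p = 0.0917 with an estimated correlation (limma). Cholesterol synthesis genes were lower in 23 of 25 (adjusted p = 0.231 with an estimated correlation, limma), and replication-dependent histones in 59 of 66 with 3 higher (adjusted p = 0.079 with an estimated correlation, limma). In Y551A-Dim, 11 of 22 inflammatory genes were lower and 2 higher (adjusted p = 0.076 with an estimated correlation, limma).

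In set 2, 9 of 24 immediate early genes and 9 of 22 growth factor feedback genes were lower in EtOH in D647V-Tetra than in WT (10 and 11 adjusted over the list alone), each at adjusted p = 0.0289 with an estimated correlation (limma). Dusp1 (-0.66) and Sgk1 (-0.31) were lower as well. Histones were higher in 33 of 66 (49 higher and 1 lower adjusted over the list alone, adjusted p = 0.277 with an estimated correlation, limma), in EtOH libraries with lower length slopes than the other EtOH libraries of set 2. Transcripts annotated as sense intronic or to be experimentally checked had a median Dex change that varied in sign between lines. It was -0.298 in WT and 0.099 in D647V of set 2, and 0.158 in WT, -0.155 in Y551A and -0.043 in Y551A-Dim of set 1. In D647V-Tetra it was 0.679, with 333 of 1374 in this group up and 2 down by edgeR, against 1984 of all 17535 genes up. Without EtOH replicates 1 and 3 of this line, the number of its called genes fell from 3367 to 377, and this group was not tested again.

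For the Dex responses and the set 1 baselines of 3 against 3 libraries, the 10 possible splits are too few for a share under 0.05. The real split called 549 genes for WT in set 1 (highest other 0), 297 for Y551A (0), 176 for Y551A-Dim (65), 165 for D647V (1), 3367 for D647V-Tetra (0), 6855 for the Y551A baseline (0) and 3757 for the Y551A-Dim baseline (1). For WT over both sets, 1 of 60 splits, the real one, reached 843 genes, and the highest other called 206. A random assignment of these libraries is thus an unlikely source of that count. The splits treat libraries as independent, and the labels do not say whether replicates came from separate cultures.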
